A study of Mus musculus with 8 samples.

How the data were processed

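RNA from pancreas cells of Dclk1-CreERT; tdTomato mice (strain CBA x C57BL/6J) was sequenced in 8 libraries, 4 of Dclk1+ and 4 of Dclk1− cells, and the grouping was taken from the sample titles. Per the labels' protocols, RNA was extracted with a micro-scale kit, samples with an RNA integrity number above 8 were kept, and RNA was amplified with the Ovation RNA-Seq V2 system before Illumina TruSeq library preparation. The labels name polyA RNA as the molecule, and do not describe the sorting gate, the animals, their sex, or any batch or pairing. They do not say that strand was used in counting, so genes that overlap on opposite strands, and genes with near-identical copies, such as trypsin and amylase genes, have uncertain counts.

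The deposited values were raw read counts per gene symbol, with 1 column per library in a single table that holds 23284 symbols. Per the submitters' processing notes, bcl2fastq 1.8.4, HTSeq 0.6.1 and the mouse build mm9 were used for all 8 libraries. The notes name Bowtie2 2.0.0 and TopHat2 2.0.4 for Dclk1− library 5 and Bowtie 0.12.7 and TopHat for the other 7 libraries, without saying what each tool did. Dclk1− libraries 5 and 6, which differ in these notes, had the highest Spearman correlation of all pairs (0.972). The gene annotation and any filters are not given in the sources used here. No normalization had been applied to the counts, which were whole numbers with a different total in each library. Every column was matched to its sample by the sample number in the title. A spreadsheet had turned 25 gene symbols into dates, of which 19 were tested and 2 called, and these were kept in the tests and not named. Of the symbols, 23062 matched a current mouse gene name or synonym in the gene table used for names. The reference genome at hand is of another build than mm9, so no coordinates are given.

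Total counts per library, the percent of counts from gene lists and the number of genes with at least 1 count were computed from the table. A single count was worth 0.102 to 0.193 CPM, and 3 counts, the expected number up to which a count of 0 remains plausible, were worth 0.306 to 0.579 CPM. Wilson intervals at the 95% level were computed for the shares of counts in single libraries. They cover counting error only, because amplified reads without molecular identifiers are not independent molecules. A chi-square comparison of counts within groups gave at least 19.8 per degree of freedom for every pair of libraries, so no pair had counts as close as 1 library deposited 2 times would.

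Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), library sizes were scaled by TMM, and a quasi-likelihood F test compared Dclk1+ with Dclk1− in a model with the group alone (6 residual degrees of freedom among samples). P-values were adjusted by Benjamini and Hochberg over the 13274 genes tested, and the threshold was 0.05. Standard errors of log2 fold changes were taken from the F statistic, and CPM values use the TMM-scaled library sizes and are given as mean ± SD. The common biological coefficient of variation was 0.625.

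Before the data were examined, 28 gene lists were fixed for the cell types, pathways and processes that pancreas cells could hold. Each was counted by edgeR calls over all genes and adjusted over the list alone, and 26 lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. Camera called 15 lists, 11 higher and 4 lower. With an estimated correlation it called 0 (smallest adjusted p = 0.588), and the fry test called 2. Fry, unlike camera, does not compare a list with other genes. Another 3 lists, for T lymphocytes, B lymphocytes and macrophages, were written after the genes with the largest decreases had been seen. Of their 28, 18 and 22 genes, 4, 2 and 12 are also in a list fixed before.

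The genes named in the text were chosen by a rule fixed before the data were examined. The rule took Dclk1, the 10 called genes with the largest increase and the 10 with the largest decrease whose groups did not overlap and whose mean was at least 10 CPM in the higher group, without predicted or unnamed gene models and small RNA genes, and from each list the 3 called genes of highest mean CPM or, where none was called, the 2 most abundant tested genes. Named genes that did not pass are given as values. The result of 1 gene that the rule takes is not reported here. Other called members of a list are named beside its count, and all further genes outside this rule were chosen after their values were seen.

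Shares of counts, total counts and genes detected were compared with exact two-sided permutation tests over the 70 assignments of 4 and 4 libraries, which allow a smallest p of 0.029. Principal components were computed on the 1000 most variable tested genes. The sex of each library was read from Xist.

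The edgeR step was tested on simulated counts with the means and dispersion of these libraries for Dclk1+ against Dclk1−. In 12990 simulated genes it called 0% of genes changed 2-fold, 24% of those changed 4-fold, 63.3% of those changed 8-fold and 70% of those changed 16-fold, with 7 false calls among 85. Differences of 2-fold were thus missed in this simulation. With a lower dispersion it called 16.3% of genes changed 2-fold and 90% of those changed 4-fold. At most 50 tested genes of each size were changed, while 4240 genes had an unadjusted edgeR p under 0.05 in the real comparison. Adjusted p-values depend on that share, so these rates need not hold for the real data. Camera, tested on simulated data, called the raised list and 0 of 24 others. The simulated genes varied independently of each other. This therefore does not show how often camera calls lists whose genes move together, such as the acinar list (estimated correlation 0.921).

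Alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors and library totals in the edgeR fit, acinar genes left out of library sizes, no filter and a stricter filter on low counts (at least 5 CPM in at least 4 libraries), DESeq2 1.42.0, limma-voom with quality weights, robust edgeR, 1 surrogate variable from sva 3.50.0, each library left out in turn, log2 shares, and a minimum of 10 counts for detection. Added after seeing the data were a fit without Dclk1− libraries 7 and 8, Rn45s and Lars2 left out of library sizes, a sex term, and a block for the number in the column names.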

Results

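RNA was sequenced from pancreas cells of mice that carry an inducible Cre recombinase at Dclk1 (Dclk1-CreERT) and a tdTomato reporter. The reporter is a red fluorescent protein that is switched on in cells where Cre has acted. The labels name the molecule as polyA RNA, but the ribosomal RNA gene Rn45s took 8.90% to 34.2% of the counts. Dclk1 encodes a doublecortin-like kinase that is widely used as a marker of tuft cells and of rare, slowly dividing epithelial cells. The 8 libraries fell into 2 groups, with 4 libraries of Dclk1+ cells (numbered 1 to 4) and 4 of Dclk1− cells (numbered 5 to 8). Each library held read counts for 23284 gene symbols. Total counts ran from 7990777 to 10282911 in the Dclk1+ libraries and from 6353841 to 7242084 in the Dclk1− libraries. The group means were 8973400 ± 956000 and 6708500 ± 389000 (SD, n = 4 each), and this difference had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries allow. Without Dclk1− library 5, 7 or 8 the groups still did not overlap, and the exact p was 0.0571, which is 2 of the 35 assignments of the 7 libraries left. The number of genes with at least 1 count was 15946 ± 692 in Dclk1+ and 15108 ± 1240 in Dclk1− libraries, a difference within the spread of the libraries (exact permutation p = 0.229, n = 4 each). Nothing in the labels said whether libraries of a group came from separate mice, so p-values measure the spread between these libraries.

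Dclk1 itself separated the groups. Its level was 131 CPM, 221 CPM, 53.3 CPM and 17.9 CPM in Dclk1+ libraries 1 to 4. In Dclk1− libraries 5 to 8 it was 7.35 CPM, 15.04 CPM, 14.9 CPM and 2.67 CPM, so every Dclk1+ library lay above every Dclk1− library. The log2 fold change was 3.40 ± 0.82 (SE, 95% interval 1.57 to 5.23). Its adjusted p in edgeR's quasi-likelihood test was 0.0503, just above the 0.05 threshold. Dclk1+ library 4 was close to the highest Dclk1− library, and without it the log2 fold change was 3.86 with an edgeR adjusted p of 0.0127. Over all alternatives tried the adjusted p of Dclk1 ran from 0.000227 to 0.157.

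The main comparison addressed which genes distinguish the Dclk1+ cells, which the series title calls progenitor cells, from Dclk1− pancreas cells. Dclk1+ cells had more RNA of genes known from ducts and other epithelia, including Spp1, Sox9, Clu and Krt8, and less RNA of genes used by lymphocytes, including Fcer2a, Zap70 and Sit1. Among Dclk1+ libraries, Spp1, Sox9, Clu and Krt8 were each lowest in library 2, which had the most Dclk1. There Clu was at 96.2 CPM and Krt8 at 4.29 CPM, close to the 89.3 and 3.82 CPM of Dclk1− library 5. Spp1, which encodes the secreted glycoprotein osteopontin, was at 1123 ± 1444 CPM in Dclk1+ and 31.1 ± 17.3 CPM in Dclk1− libraries (SD, n = 4 each), a log2 fold change of 5.17 ± 1.12 (SE, edgeR adjusted p = 0.0487). Most of its Dclk1+ mean came from library 3 at 3259 CPM, with 73.5 to 608.5 CPM in the other Dclk1+ libraries. Sox9, a transcription factor of duct cells, was at 125 ± 116 CPM against 6.03 ± 4.80 CPM, a log2 fold change of 4.36 ± 0.89 (edgeR adjusted p = 0.0469). In the other direction Fcer2a, the low-affinity IgE receptor of B cells, was at 24.1 ± 24.7 CPM against 476 ± 116 CPM, with a log2 fold change of -4.30 ± 0.83 (edgeR adjusted p = 0.0469). Of 13274 genes tested, 463 passed the adjusted p threshold of 0.05. Among these, 328 were higher and 135 lower in Dclk1+ cells, and each had at least a 2-fold difference. Of the 463 genes, 455 had no overlap between the CPM values of the groups. Among all tested genes 2867 (21.6%) had no overlap, where chance gives 2.86%.

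These calls lay close to the threshold. The smallest adjusted p was 0.0467 and 2807 genes were under 0.1, so small changes in the fit moved many genes across it. No gene was called by edgeR when Dclk1+ library 1, 2 or 3 or any single Dclk1− library was left out, although 3092 to 4005 genes then had an unadjusted p under 0.05. Without Dclk1+ library 4 there were 1640 genes higher and 841 lower. DESeq2 called 2565 genes higher and 1122 lower on all 8 libraries. With limma-voom the calls were 2436 higher and 2254 lower, so the higher share was 51.9% in place of 70.8%.

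**Figure D1:**
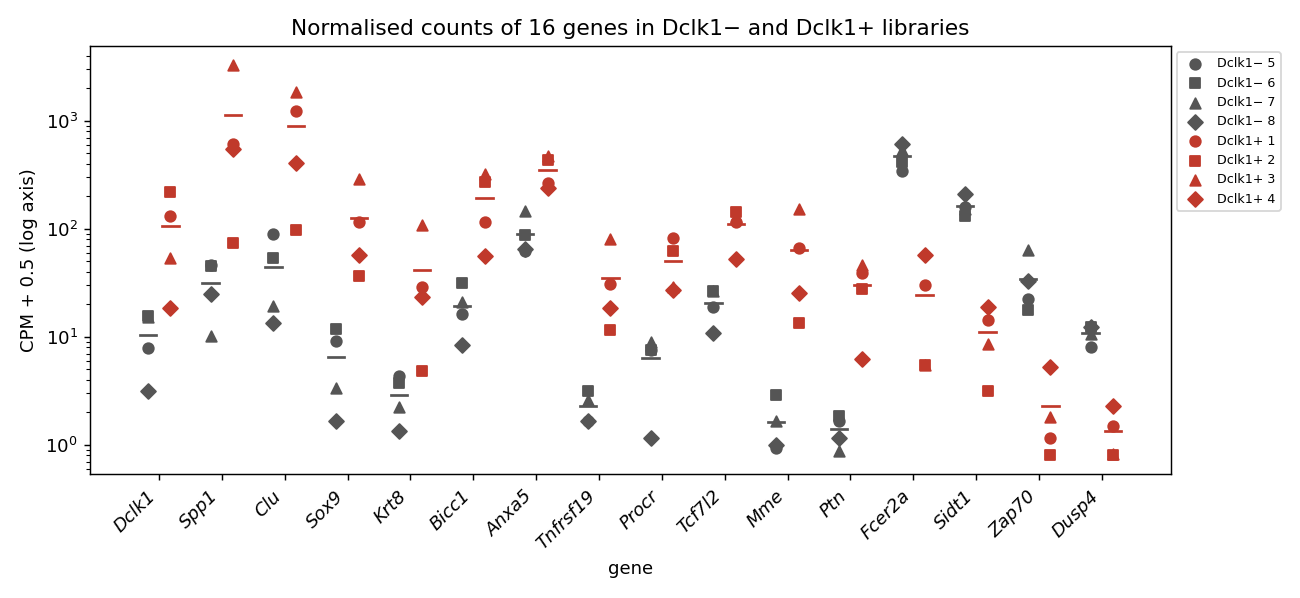
Normalised counts of 16 genes named in the text, as CPM + 0.5 on a log axis, with 1 point per library (grey, Dclk1−; red, Dclk1+) and a bar at the mean of each group of 4. The groups do not overlap for any of these genes, and the Dclk1+ points spread widely, from 73.5 to 3259 CPM for Spp1.

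Among called genes that met the naming rule, the 10 with the largest increases were Cldn2, Mme, Dnahc6, Bmp2, Spp1, Crp, Ptn, Ces1d, Dpysl4 and Olfml2a, with log2 fold changes from 5.95 for Cldn2 down to 4.73 for Olfml2a. Cldn2, a tight junction claudin of leaky epithelia, averaged 22.2 ± 22.3 CPM in Dclk1+ and 0.310 ± 0.526 CPM in Dclk1− libraries. It was at 0 CPM in Dclk1− libraries 7 and 8, and at 1.84 CPM in Dclk1+ library 2 against 1.09 CPM in Dclk1− library 6. Mme, which encodes the membrane peptidase neprilysin, was at 63.8 ± 62.7 CPM against 1.13 ± 0.92 CPM, a log2 fold change of 5.77 ± 0.94. Bmp2, a bone morphogenetic protein, was at 63.5 ± 94.6 CPM against 1.47 ± 1.29 CPM, with most of the mean from Dclk1+ library 1 at 204.9 CPM. Ptn, which encodes the growth factor pleiotrophin, was at 29.4 ± 17.5 CPM against 0.891 ± 0.440 CPM. Ces1d, a carboxylesterase, reached 357 CPM in Dclk1+ library 3 and lay between 48.3 and 54.8 CPM in the other Dclk1+ libraries. The axonemal dynein chain gene Dnahc6 and Crp, which encodes C-reactive protein, had log2 fold changes of 5.46 ± 1.23 and 5.07 ± 1.16. Dnahc6 was at 42.4 CPM in Dclk1+ library 1 and at 3 to 5.18 CPM in the other Dclk1+ libraries. The log2 fold changes of Dpysl4 and Olfml2a were 4.76 ± 1.08 and 4.73 ± 0.95. In Dclk1+ library 2 Crp and Dpysl4 were at 3.16 and 1.53 CPM, against at most 2.06 and 0.728 CPM in Dclk1− libraries.

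Under the same rule the 10 largest decreases were in Cnga1, Scn4a, Aim1l, Sit1, Fcer2a, Zap70, Sla2, Cacna1i, Sidt1 and Tmem108, with log2 fold changes from -5.69 for Cnga1 to -3.92 for Tmem108. Cnga1, a subunit of a cyclic nucleotide-gated channel, was at 10.7 ± 1.84 CPM in Dclk1− libraries and at most 0.333 CPM in any Dclk1+ library. Zap70, the kinase bound by the T cell receptor, was at 33.8 ± 20.6 CPM in Dclk1− and 1.77 ± 2.05 CPM in Dclk1+ libraries. Sit1 and Sla2, adaptors that dampen lymphocyte receptor signals, had log2 fold changes of -4.31 ± 0.98 and -3.97 ± 0.89. Cacna1i, a T-type calcium channel subunit, had a log2 fold change of -3.93 ± 0.89. Sidt1 was the most abundant of the 10 after Fcer2a, at 162 ± 33.0 CPM in Dclk1− and 10.7 ± 6.82 CPM in Dclk1+ libraries. Scn4a, a sodium channel subunit best known from muscle, had a log2 fold change of -4.90 ± 0.87, and Aim1l one of -4.36 ± 0.58.

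Duct and epithelial genes were higher as groups. Of 16 ductal markers tested, 5 were called higher (Sox9, Spp1, Slc4a4, Bicc1 and Anxa5), none was called lower and 11 did not pass, and adjusted over the list alone 14 were higher and 1 lower. Bicc1, an RNA-binding protein of duct and kidney epithelia, was at 192 ± 126 CPM against 18.8 ± 9.69 CPM, and Anxa5 at 352 ± 119 CPM against 89.7 ± 38.7 CPM. In Dclk1+ library 2, where Sox9 and Spp1 had their lowest Dclk1+ values, Bicc1 was at 273.8 CPM and Anxa5 at 435.2 CPM. Each was exceeded only in Dclk1+ library 3, so these genes did not follow Sox9 and Spp1 across libraries. The median log2 fold change of the list was 3.86. Of 15 general epithelial markers, Krt8 alone was called (40.7 ± 45.4 CPM against 2.42 ± 1.37 CPM), 11 were higher adjusted over the list alone and 0 were lower, with a median of 3.53 and a positive fold change in all 15. The set test camera called both lists higher with its preset correlation (adjusted p = 5.75e-06 for ductal and 5.47e-05 for epithelial genes). With an estimated correlation neither passed (adjusted p = 0.588 for each). The mean log2 CPM of the ductal list was 7.68 in Dclk1+ library 3, 6.31 in library 1, 5.62 in library 4 and 4.17 in library 2, and at most 3.70 in the Dclk1− libraries. The epithelial list overlapped, with Dclk1+ library 2 at 2.59 and Dclk1− libraries 5 and 6 at 2.96 and 2.63.

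Of the genes in the acinar, Reg, endocrine and chaperone lists, Clu alone was called. None of 31 acinar enzyme genes was called, over all genes or adjusted over the list alone, and their median log2 fold change was 0.21. Ctrb1 and Cpb1, which encode digestive proenzymes, had log2 fold changes of 0.64 ± 0.98 and 0.20 ± 0.97 (edgeR adjusted p = 0.682 and 0.903). The acinar list took 5.60% ± 2.89 of the counts in Dclk1+ and 4.32% ± 4.37 in Dclk1− libraries (SD, n = 4 each, exact permutation p = 0.629). Camera called the acinar list higher (adjusted p = 0.0149, or 0.737 with an estimated correlation), but this call was lost without Dclk1− library 7 or 8 or Dclk1+ library 1 or 4, and the median turned to -0.45 under limma-voom. The 5 acinar transcription factor genes tested held no call (camera adjusted p = 0.363), and their most abundant members, Xbp1 and Nr5a2, had log2 fold changes of 0.39 ± 0.27 and 3.34 ± 1.11. In the Reg and acute pancreatitis list 1 of 10 genes was called over all genes and 1 adjusted over the list alone. This was Clu, which encodes the secreted chaperone clusterin, at 898 ± 794 CPM against 43.5 ± 35.3 CPM, and the list as a whole did not pass (camera adjusted p = 0.0529). It passed without Dclk1− library 5 or Dclk1+ library 2 or 3, and with a stricter filter on low counts, while with an estimated correlation on all 8 libraries its adjusted p was 0.655. None of 12 endocrine hormone and granule genes was called and 4 were higher adjusted over the list alone. The list was called by camera (median 2.46, adjusted p = 0.0119, or 0.588 with an estimated correlation), and this call was lost without Dclk1+ library 3 or 4, without Dclk1− libraries 7 and 8, and with the stricter filter. Somatostatin (Sst) was at 0 CPM in Dclk1+ library 1 and between 69.2 and 262.5 CPM in libraries 2 to 4, against 0 to 10.9 CPM in Dclk1− libraries (edgeR adjusted p = 0.112), and the glucagon gene Gcg had an adjusted p of 0.414. Of 3 endocrine transcription factor genes that could be tested none was called and 2 were higher adjusted over the list alone. Hhex, a homeobox gene of delta cells, had a log2 fold change of 0.07 ± 0.66. The chaperone and unfolded protein response list did not pass (24 genes, 0 called, camera adjusted p = 0.818). Its median was -0.04 and its mean -0.0040 while camera put it higher, and Hsp90b1 and Hspa5 had log2 fold changes of 0.70 ± 0.57 and -0.01 ± 0.33.

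Fibroblast and pericyte markers were also higher in Dclk1+ cells as groups. Of 25 fibroblast and stellate cell genes none was called over all genes, 24 had a positive fold change, and adjusted over the list alone 21 were higher and 1 lower. Fbn1, which encodes fibrillin, was at 5353 ± 5957 CPM in Dclk1+ and 732 ± 599 CPM in Dclk1− libraries (edgeR adjusted p = 0.0755), and the proteoglycan gene Dcn at 4919 ± 4715 CPM against 851 ± 646 CPM (adjusted p = 0.0937). The list median was 2.23, and camera called it higher (adjusted p = 7.16e-08, or 0.588 with an estimated correlation). Fibroblast genes took 3.28% ± 2.31 of the counts in Dclk1+ against 0.651% ± 0.467 in Dclk1− libraries (exact permutation p = 0.0571, adjusted p = 0.0857, n = 4 each). The share was highest in Dclk1+ library 2, at 6.51% (95% Wilson interval 6.50% to 6.53%), which was also the library with the most Dclk1. Of 15 pericyte and smooth muscle genes none was called and 11 were higher adjusted over the list alone (median 2.69, camera adjusted p = 3.66e-05, or 0.588 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain gene, was at 958 CPM in Dclk1+ library 1 and at most 39.2 CPM in every other library, and Pdgfrb was at 112 ± 82.5 CPM against 19.2 ± 10.8 CPM (adjusted p = 0.0569). None of 21 endothelial genes was called, over all genes or adjusted over the list alone (median 1.81). Camera called that list (adjusted p = 0.00712, or 0.702 with an estimated correlation), and the call was lost without Dclk1− library 7 or Dclk1+ library 1, without Dclk1− libraries 7 and 8, with 1 surrogate variable and under limma-voom. The endothelial share of counts was 0.265% ± 0.209 in Dclk1+ and 0.0940% ± 0.0856 in Dclk1− libraries (exact permutation p = 0.143, adjusted p = 0.161, n = 4 each), and the list mean of Dclk1+ library 2 (2.44) lay below those of Dclk1− libraries 5 and 6 (4.68 and 5.49). Pecam1 had a log2 fold change of 0.02 ± 0.74 and Ptprb one of 1.67 ± 1.57.

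Nerve, mesothelial and fat markers gave no list that passed camera. Of 11 Schwann and glial genes 0 were called, while 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.804). Their median was -0.02 and their mean 0.61, with Pmp22 at 2.19 ± 0.64 and Scn7a at 2.90 ± 0.84 on the log2 scale. Of 7 neuronal genes 0 were called, with 1 higher and 1 lower adjusted over the list alone (median 1.47, camera adjusted p = 0.157). Dcx, the doublecortin gene related to Dclk1, was at 23.7 ± 29.8 CPM against 0.730 ± 0.767 CPM with an adjusted p of 0.0563, and Syp had a log2 fold change of 0.49 ± 0.66. The 7 mesothelial genes (median 1.20, camera adjusted p = 0.783) and 5 adipocyte genes (median 0.64, camera adjusted p = 0.486) held no call over all genes or adjusted over the list alone. Their most abundant members were Wt1 at 1.97 ± 0.95 and Rspo1 at 1.24 ± 0.74, and Fabp4 at 1.04 ± 1.07 and Pnpla2 at -0.51 ± 0.61 on the log2 scale. The shares of counts from the pericyte, glial, neuronal and endocrine hormone lists were higher, and that of the erythroid list lower, in Dclk1+ libraries, each with an exact permutation p of 0.0286 (n = 4 each). None passed after adjustment over the 9 lists compared (adjusted p = 0.0514). That exact p is the smallest that 4 against 4 libraries allow, so larger differences in these lists would not have lowered the adjusted value.

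Tuft cell genes did not pass as a list. Of 11 tested, Ptgs1 alone was called, over all genes and adjusted over the list alone. It encodes cyclooxygenase 1, and was at 186 ± 146 CPM in Dclk1+ against 28.6 ± 15.1 CPM in Dclk1− libraries, a log2 fold change of 2.70 ± 0.59 (edgeR adjusted p = 0.0490). Ptgs1 was highest in Dclk1+ library 2, at 402.9 CPM, where the mean of the tuft list was the lowest of all 8 libraries (1.45 log2 CPM). The list had 5 positive and 6 negative fold changes, a median of -0.11 and a camera adjusted p of 0.157. Without Dclk1+ library 4 it was called lower, with a median of -1.30 (camera adjusted p = 0.0111, with a range of 0.0111 to 0.816 over the alternatives that keep the preset correlation). On all 8 libraries its adjusted p was 0.702 with an estimated correlation. The members with the largest negative fold changes, chosen after their values were seen, were Spib at -2.70, Vav1 at -2.32, Plcb2 at -2.32 and Plcg2 at -2.21 on the log2 scale, none of them called. Lymphocytes also express these genes, and the T and B lymphocyte lists had medians of -3.23 and -3.33.

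Genes linked to stem and progenitor cells were higher as a list. Of 31 tested, Procr, Sox9 and Tnfrsf19 were called higher and 28 did not pass, and adjusted over the list alone 9 were higher and 1 lower (median 1.14). Procr, the endothelial protein C receptor used as a marker of several stem cell populations, was at 49.8 ± 27.0 CPM against 5.81 ± 3.50 CPM. Tnfrsf19, a Wnt target and receptor known from intestinal stem cells, was at 34.8 ± 31.1 CPM against 1.78 ± 0.74 CPM. Of 20 Wnt pathway genes 4 were called, all higher (Tcf7l2, Fzd1, Fzd7 and Lrp5), and adjusted over the list alone 12 were higher and 2 lower (median 1.88). The 2 lower genes were Lef1 at -3.57 and Tcf7 at -3.07 on the log2 scale (edgeR adjusted p = 0.0503 and 0.0601), and both are also in the T lymphocyte list. The transcription factor gene Tcf7l2 was at 110 ± 40.0 CPM against 20.2 ± 7.50 CPM, the receptor gene Fzd1 at 96.7 ± 51.4 CPM against 14.6 ± 8.44 CPM, and the co-receptor gene Lrp5 at 56.7 ± 19.8 CPM against 9.18 ± 5.22 CPM. None of 9 Hedgehog pathway genes was called and 3 were higher adjusted over the list alone (median 2.16), with Cdon at 2.39 ± 0.62 and Gli3 at 2.71 ± 0.74 on the log2 scale. Its mean was highest in Dclk1+ library 2 (6.32 log2 CPM) and, among Dclk1− libraries, in library 7 (4.59), as was that of the fibroblast list (10.24 and 8.28), which shares Gli1 with it. In the MAPK feedback list 2 of 17 genes were called higher (Spred1 and Etv5) and 1 lower (Dusp4), and adjusted over the list alone 10 were higher and 2 lower (median 2.10). Dusp4, a phosphatase that acts on MAP kinases, was at 0.853 ± 0.695 CPM in Dclk1+ and 10.4 ± 2.01 CPM in Dclk1− libraries, while Spred1, an inhibitor of Ras signalling, was at 59.2 ± 11.6 CPM against 13.6 ± 7.46 CPM. Camera called these 4 lists higher, with adjusted p of 0.00556 for stem and progenitor genes, 0.000724 for Wnt, 0.0119 for Hedgehog and 0.00556 for MAPK. With an estimated correlation each had an adjusted p of 0.588. Fry, which tests whether the genes of a list move on balance in a single direction, called the Wnt and neuronal lists (adjusted p = 0.0288 each).

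Notch pathway genes did not pass as a list (18 tested, 0 called, 5 higher and 2 lower adjusted over the list alone, median 1.30, camera adjusted p = 0.12), and passed without Dclk1+ library 2 (on all 8 libraries, adjusted p = 0.588 with an estimated correlation). On the log2 scale Notch2 was at 0.36 ± 0.33 and Notch1 at -0.23 ± 0.50. Of 19 genes for cell cycle inhibitors and quiescence, Klf9 alone was called (93.0 ± 49.9 CPM against 17.2 ± 6.72 CPM), 5 were higher and 2 lower adjusted over the list alone, and the list did not pass (median 0.10, camera adjusted p = 0.881). Of 25 immediate early genes Dusp1 and Cyr61 were called higher and Egr3 lower, with 9 higher and 4 lower adjusted over the list alone (median 0.40, camera adjusted p = 0.447). Dusp1 was at 358 ± 149 CPM against 76.8 ± 31.9 CPM, Cyr61 at 68.6 ± 44.6 CPM against 7.22 ± 4.58 CPM, and Egr3 at 2.52 ± 1.38 CPM against 14.9 ± 6.09 CPM.

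Cell cycle, ribosomal protein and respiratory chain genes were lower as lists. Of 40 proliferation genes 39 had a negative fold change and 0 were called, over all genes or adjusted over the list alone (median -0.67, camera adjusted p = 5.27e-05, or 0.655 with an estimated correlation). The list mean was 4.07 to 4.59 log2 CPM in Dclk1− libraries. In Dclk1+ libraries 1 to 4 it was 2.63, 1.38, 3.79 and 4.78, the last being the highest of all 8, beside leukocyte list means of 4.94, 2.54, 5.89 and 8.82. Mki67 was at 151 ± 120 CPM against 364 ± 263 CPM and Top2a at 75.5 ± 66.2 CPM against 115 ± 61.2 CPM (edgeR adjusted p = 0.304 and 0.586). All 40 cytosolic ribosomal protein genes had a negative fold change and 0 were called, but 39 were lower adjusted over the list alone (median -1.69, camera adjusted p = 2.18e-09, or 0.588 with an estimated correlation). These genes have many processed pseudogenes, so their counts are uncertain where reads were shared. Rpl4 was at 850 ± 199 CPM against 1830 ± 709 CPM and Rps3 at 461 ± 175 CPM against 1369 ± 1018 CPM. The mean log2 CPM of the ribosomal protein list was 8.06 and 7.43 in Dclk1− libraries 7 and 8, against 6.00 and 5.82 in libraries 5 and 6 and 4.997 to 6.06 in Dclk1+ libraries. Without libraries 7 and 8 the median was -0.35. The oxidative phosphorylation list held 0 calls among 43 genes, over all genes or adjusted over the list alone (median -0.60, camera adjusted p = 0.00792, or 0.708 with an estimated correlation), with Atp5b at -0.77 ± 0.46 and Atp5a1 at -0.60 ± 0.38 on the log2 scale. That call was lost without Dclk1− library 7, and the median turned to 0.23 without libraries 7 and 8. With 1 surrogate variable in the fit the list was called in the opposite direction (median 0.25, camera adjusted p = 0.0473).

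**Figure D2:**
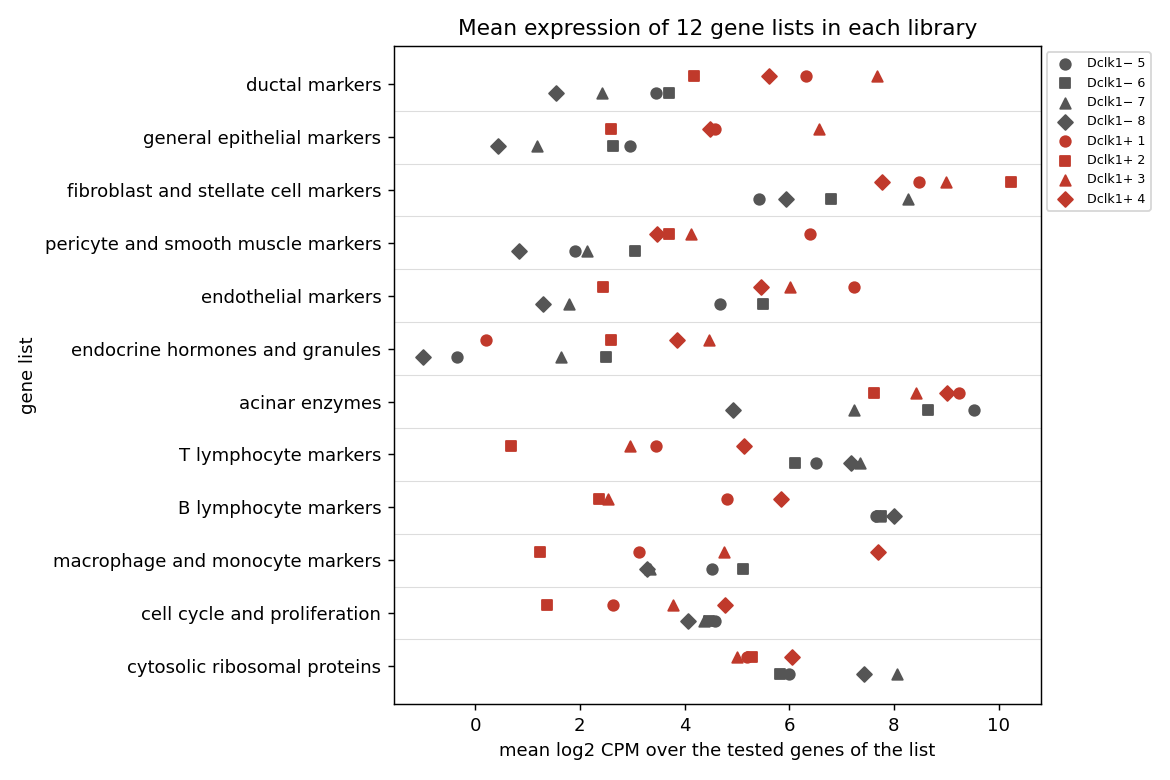
Mean log2 CPM over the tested genes of 12 gene lists, with 1 point per library (grey, Dclk1−; red, Dclk1+). T and B lymphocyte lists lie lower in every Dclk1+ than in any Dclk1− library, the ductal list lies higher in every Dclk1+ library, and Dclk1+ library 4 has the highest macrophage value, 7.70.

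Lymphocyte genes were lower in Dclk1+ libraries, and macrophage genes did not pass. Of the 28 genes in the leukocyte list fixed beforehand none was called, 4 were lower adjusted over the list alone, and 14 had a positive and 14 a negative fold change (median -0.20, camera adjusted p = 0.0022, or 0.702 with an estimated correlation). Over the alternatives that keep the preset correlation its median ran from -2.79 to 0.19. The list mean was 8.82 log2 CPM in Dclk1+ library 4 and 2.54 to 5.89 in the other Dclk1+ libraries, against 7.11 to 7.48 in Dclk1− libraries. Cd74 and H2-Aa, genes of antigen presentation on MHC class II, had log2 fold changes of -1.26 ± 1.13 and -1.34 ± 1.10. Separate lists for lymphocytes and macrophages were written after the genes with the largest decreases had been seen, so they are not independent of them. All 27 T lymphocyte genes tested had a negative fold change, with a median of -3.23, and 4 were called lower (Cd247, Zap70, Lat and Themis). Of 18 B lymphocyte genes 17 were negative, with a median of -3.33, and Pax5, Cd22 and Fcer2a were called lower. Adjusted over the list alone 23 T and 17 B lymphocyte genes were lower. Camera gave adjusted p of 4.49e-15 and 1.93e-11, or 0.169 for each with an estimated correlation. None of 22 macrophage and monocyte genes was called, over all genes or adjusted over the list alone (median 1.86, camera adjusted p = 0.776), and without Dclk1+ library 4 the median was -0.51. Erythroid genes were lower in Dclk1+ libraries, mostly against Dclk1− libraries 7 and 8, but not called (4 tested, 4 lower adjusted over the list alone, too few for a set test). Their mean log2 CPM was 9.02 and 9.49 in those 2 libraries. It was 3.75 and 4.09 in Dclk1− libraries 5 and 6, which overlapped the 1.88 to 3.94 of the Dclk1+ libraries. Alas2, the erythroid enzyme of haem synthesis, was at 1490 and 1205 CPM in Dclk1− libraries 7 and 8 and between 8.71 and 36.2 CPM in the other 6 libraries, and Bpgm had a log2 fold change of -4.23 ± 1.09 (edgeR adjusted p = 0.0503 and 0.0539).

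The libraries within each group were not alike. On the first principal component, with 61.8% of the variance of the 1000 most variable genes, Dclk1+ libraries 1, 2 and 3 scored between 65.1 and 66.9, Dclk1+ library 4 scored 2.52, and the Dclk1− libraries scored between -90.5 and -15.2. Spearman correlations of Dclk1+ library 4 were 0.786 to 0.890 with the Dclk1− libraries and 0.702 to 0.826 with the other Dclk1+ libraries. Leukocyte markers took 2.84% of its counts (95% Wilson interval 2.83% to 2.85%), against 0.0288% to 0.412% in the other Dclk1+ libraries and 1.32% to 2.19% in the Dclk1− libraries. Dclk1− libraries 7 and 8 held the most counts of the ribosomal RNA gene Rn45s, 34.2% and 26.1%, against 8.90% to 18.3% elsewhere, and the most beta globin (Beta-s), 1.34% and 1.32%, against at most 0.0404% elsewhere. The widest 95% Wilson interval of these shares was ± 0.036 percentage points, which covers counting error only. The 10 most abundant genes took 22.7% ± 3.43 of the counts in Dclk1+ and 27.7% ± 10.5 in Dclk1− libraries (exact permutation p = 0.457, n = 4 each).

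By the level of Xist, the RNA expressed from the inactive X chromosome, Dclk1+ libraries 3 and 4 and Dclk1− library 8 came from females and the other 5 from males. Within males (2 Dclk1+ and 3 Dclk1− libraries) the mean log2 CPM of Dclk1 was higher by 3.82, that of the ductal list by 2.05 and that of the fibroblast list by 2.52 in Dclk1+ libraries. Within females, with 2 Dclk1+ libraries and 1 Dclk1− library, these differences were 3.41, 5.11 and 2.45. The T lymphocyte list differed by -4.59 in males and -3.14 in females, and the ribosomal protein list by -1.39 and -1.90. The macrophage list differed by -2.14 in males and by 2.95 in females. The proliferation list differed by -2.48 in males and by 0.21 in females, and the acinar list by -0.05 and 3.79. The stem and progenitor list was higher by 0.66 and 2.13. Every female difference compares Dclk1+ libraries 3 and 4 with Dclk1− library 8 alone. The macrophage means of these libraries were 4.75, 7.70 and 3.28 log2 CPM. Unlike signs in males and females thus cannot be told apart from differences between single libraries. With a sex term in the edgeR fit 1375 genes were called higher and 666 lower.

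**Figure D3:**
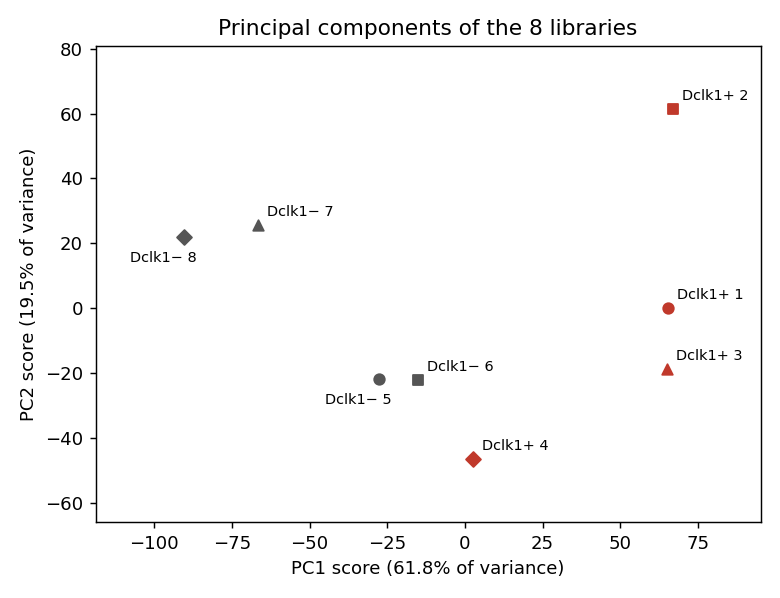
Scores of the 8 libraries on the first and the second principal component of log2 CPM for the 1000 most variable tested genes (grey, Dclk1−; red, Dclk1+). Dclk1+ library 4 lies between the other Dclk1+ libraries and the Dclk1− libraries on the horizontal axis.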

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

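The values in this part were picked by a fixed test for a library far from the other 3 of its group, which picks about 1 group in 20 by chance. It was run on 246 groups of 4 values and picked 7, where chance would give about 12.3, so the number of such values is no larger than chance gives. The tests of explanations in this part were chosen after the results were seen.

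In Dclk1+ library 3, Ces1d was at 357 CPM, the mean log2 CPM of neuronal markers was 2.81, and that of chaperone and unfolded protein response genes was 6.51, lower than in the other Dclk1+ libraries. In Dclk1+ library 4 leukocyte markers took 2.84% of the counts. In Dclk1+ library 1 pericyte and smooth muscle genes took 0.264% of the counts (95% Wilson interval 0.261% to 0.268%). In Dclk1− library 8, Procr was at 0.668 CPM and the mean log2 CPM of endocrine transcription factors was 2.24, both below the other Dclk1− libraries.

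The number of called genes, 463 by edgeR, could come from how the libraries happened to be divided. Chance can be excluded only at the smallest share these libraries allow: of the 35 splits of the 8 libraries into 4 and 4, 1 split, the real one, gave at least as many, and the highest count in any other split was 0, with 32 to 2792 genes at an unadjusted p under 0.05. The other splits mix the groups, which widens the spread within them, and the count of the real split was itself 0 without any single library other than Dclk1+ library 4. Sex as the whole source is argued against too, since 462 of the 463 genes were still called with a sex term. What stays open is what the libraries hold, because the labels describe neither the gate nor the animals.

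A rise of all leukocyte types alike in the Dclk1− libraries as the source of their higher lymphocyte genes is argued against by the difference between T lymphocyte and macrophage means within each library, which was 2.73 ± 1.48 log2 units in Dclk1− and -1.15 ± 1.29 in Dclk1+ libraries (SD, n = 4 each), with no overlap (exact permutation p = 0.0286, the smallest that 4 against 4 allow). Both lists were written after the largest decreases in these data had been seen, so that p is not an independent test. Within males the macrophage list too was lower in Dclk1+ libraries (a difference of -2.14, against -4.59 for the T list). In females, with 1 Dclk1− library, it was higher by 2.95. The T lymphocyte median stayed at or below -3.135 under 5 other scalings. These left the median of all genes between -0.0806 and 0.0181, so they differ too little to test scaling as the source. Lymphocytes in the Dclk1− libraries remain a candidate explanation, with T and B medians of -3.228 and -3.331, Cd3e at 229 to 1316 CPM in Dclk1− and 2.96 to 155 CPM in Dclk1+ libraries, and Cd79a at a mean of 375 CPM against 34.1 CPM. The labels name no gate that would remove leukocytes, and of the 28 T and 18 B lymphocyte genes 4 and 2 are also in lists fixed before, and 0 and 1 were above 10 CPM in every Dclk1+ library.

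The ribosomal protein genes were lower in Dclk1+ libraries mostly against Dclk1− libraries 7 and 8. Without both, 37 of 40 genes were still negative, with a median of -0.35 (camera adjusted p = 0.003, with a range of 9.67e-14 to 0.0419 over the alternatives that keep the preset correlation, and 0.588 with an estimated correlation on all 8 libraries), but the list mean of Dclk1+ library 4 (6.06) lay above those of the 2 Dclk1− libraries left (6.00 and 5.82). Whether these 2 libraries could be the whole cause thus cannot be told apart from a difference between the groups, because only 2 Dclk1− libraries are left. The same libraries had the most Rn45s, globin and T lymphocyte RNA, and the part of each was not tested.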

How the results depend on the processing

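Alternatives without Dclk1− libraries 7 and 8, without Rn45s and Lars2 in the library sizes, with a sex term or with a block for the column number were chosen after seeing the data. The sign of the 463 called genes held in 461 to 463 of them under every alternative except the stricter filter, which tested 435 of them and kept the sign of all 435. Of the 463 genes, 455 had no overlap between the groups, and each had at least a 2-fold difference. Their sign could thus hardly turn in fits to the same libraries, and its holding is no independent support for them. The number of calls did not hold. For most changes the cause was not tested. Calls higher and lower in Dclk1+ were 665 and 193 with DESeq2 size factors, 225 and 96 with upper-quartile factors, 793 and 264 without a filter, 613 and 237 with the stricter filter, 2565 and 1122 with DESeq2, 2436 and 2254 with limma-voom, 185 and 71 with robust edgeR, 1375 and 666 with a sex term, and 1106 and 514 with the column block. They were 0 and 0 with library totals only, with 1 surrogate variable, and without libraries 7 and 8, where 3961, 3078 and 3588 genes had an unadjusted edgeR p under 0.05. Leaving out single libraries gave 0 to 1640 higher and 0 to 841 lower calls, with fewer libraries in each fit. The high ends came without Dclk1+ library 4 and the other 7 gave 0.

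The log2 fold change of Dclk1 was positive throughout, from 2.746 to 3.862 with single libraries left out. It passed the threshold with DESeq2 size factors (3.513, adjusted p = 0.0454), without the acinar list in library sizes (3.402, 0.05), without a filter (3.52, 0.0406), with the stricter filter (3.451, 0.0439), with DESeq2 (3.517, 0.000227), with limma-voom (2.641, 0.00906), without Rn45s and Lars2 in library sizes (3.417, 0.0488), with a sex term (3.792, 0.0164) and with the column block (3.172, 0.0183). Over all alternatives its adjusted p ran from 0.000227 to 0.157. The number of lists called by camera, 15, lay between 11 and 18, and was 0 with an estimated correlation. The difference in total counts lay between 1828500 and 2592500 with single libraries left out, with an exact permutation p of 0.0571 without Dclk1− library 5, 7 or 8, where the groups still did not overlap. The difference in acinar share lay between -0.0118 and 3.17 percentage points, and turned without Dclk1− library 8.

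Named genes that changed sign were called in neither fit. Hspa5 turned to 0.0966 with DESeq2 size factors, 0.0567 with library totals, 0.0647 without a filter, 0.0462 with the stricter filter, 0.0969 with DESeq2, 0.109 with the sex term and 0.0144 with the column block. Under limma-voom Ctrb1 was at -0.238, Cpb1 at -0.515, Pecam1 at -0.662 and Pnpla2 at 0.302. With 1 surrogate variable Ctrb1 was at -0.349, Cpb1 at -0.883, Hhex at -0.13, Ptprb at -0.661, Pecam1 at -0.590, Fabp4 at -0.508, Pnpla2 at 0.784, Atp5b at 0.152 and Atp5a1 at 0.135. Without libraries 7 and 8 Ctrb1 was at -0.0126, Cpb1 at -0.556, Pecam1 at -0.147, Pnpla2 at 0.765, Notch1 at 0.0419, Atp5b at 0.121 and Atp5a1 at 0.140. Hhex was at -0.541 with the sex term and -0.526 with the column block, and Pecam1 at -0.368 with that block. With single libraries left out the ranges were -0.161 to 0.161 for Hspa5, -0.204 to 1.137 for Cpb1, -0.539 to 0.411 for Pecam1, -0.617 to 0.0880 for Notch1 and -0.696 to 0.426 for Hhex.

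The set test changed direction for the following lists, given with their medians. These were acinar enzymes at -0.448 with limma-voom, -0.731 with a surrogate variable and -0.429 without libraries 7 and 8, and oxidative phosphorylation at 0.065, 0.253 (called higher, camera adjusted p = 0.0473) and 0.226 under the same changes. Endothelial genes were at 0.0418 and quiescence genes at 0.162 with a surrogate variable, and quiescence genes at 0.153 without a filter. Mesothelial genes were at -0.120 without a filter and 0.945 with the column block, Schwann genes at -0.689 with the stricter filter, chaperones at -0.0284 with limma-voom and acinar transcription factors at -0.175 without libraries 7 and 8. With single libraries left out, medians ran from 0.602 to 1.547 for mesothelial, -0.0746 to 0.165 for chaperone and -0.0842 to 0.370 for quiescence genes. Calls lost or gained by camera were those of Reg genes (gained, medians 0.232 with the stricter filter and 1.246 with the column block), endocrine hormones (lost, 2.179 with that filter and 3.203 without libraries 7 and 8), and endothelial genes (lost, 0.660 with limma-voom and 1.162 without libraries 7 and 8). With single libraries left out, medians ran from -0.170 to 1.078 for acinar enzymes (lost without Dclk1− library 7 or 8 or Dclk1+ library 1 or 4), -0.152 to 1.908 for Reg genes, 2.249 to 4.643 for endocrine hormones, -1.303 to 0.719 for tuft genes, 0.949 to 2.959 for endothelial genes, 0.694 to 1.658 for Notch and -0.785 to -0.152 for oxidative phosphorylation. The macrophage list was at -0.414 with limma-voom, -1.271 with the sex term, -0.360 with the column block, and between -0.509 and 2.213 with single libraries left out.

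The labels pair no libraries, because the sample numbers are not shared between the groups. The block above uses the numbers in the column names, which libraries may share without being pairs, since the correlations of deviations from the group means were 0.139, 0.0555, -0.109 and 0.273. With the acinar list left out of the counts its own set test has no value. Another 3 DESeq2 results for named genes had no adjusted p and are not counted.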

Other observations

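The tests of explanations in this part were chosen after the results were seen. The genes named in the next paragraph lie outside the rule for named genes and were chosen after their values were seen.

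Several genes of transcription factors and receptors were called higher in Dclk1+ cells. Among them were Yap1 and Wwtr1, the coactivators of the Hippo pathway, with log2 fold changes of 2.35 ± 0.54 and 2.57 ± 0.58 (SE), and their DNA-binding partner Tead1, at 200.2 ± 113 CPM in Dclk1+ against 18.8 ± 10.5 CPM in Dclk1− libraries (SD, n = 4 each). Gata6, a transcription factor of pancreas development, and Erbb2, a receptor tyrosine kinase, were also called, with log2 fold changes of 3.67 ± 0.63 and 3.41 ± 0.67. The metallothionein genes Mt1 and Mt2, which encode metal-binding proteins, rose with the smallest spread of these, at 2.03 ± 0.33 and 1.77 ± 0.35. Among the genes called lower were Foxp3, the transcription factor of regulatory T cells, and Ikzf3 and Bach2, transcription factors of lymphocytes, with log2 fold changes of -3.63 ± 0.61, -3.24 ± 0.73 and -2.37 ± 0.42. No set test was run on these genes, and all the calls rest on edgeR adjusted p between 0.0467 and 0.0492. Of the tuft cell genes too low to be tested, Trpm5, a taste transduction channel, was at no more than 0.588 CPM in any library. Pou2f3, a transcription factor of tuft cells, was at 1.10 to 1.67 CPM in the Dclk1+ libraries, above the floor of 3 counts in each, and at 0.147, 0, 0 and 1.34 CPM in Dclk1− libraries 5 to 8, so the groups overlapped.

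Counts of Lars2, the mitochondrial leucyl-tRNA synthetase gene, followed those of the ribosomal RNA gene Rn45s across all 8 libraries. Lars2 was between 4.55% and 6.09% of Rn45s, and the SD of the log2 ratio was 0.141, the smallest of 1833 genes with a mean of at least 100 CPM (median SD 1.23, next Ubb at 0.174). Pearson's r was 0.989 (exact permutation p = 2.48e-05) and Spearman's rho was 1 (exact permutation p = 4.96e-05, the smallest that a two-sided test on the ranks of 8 libraries can give), and r was 0.936 without Dclk1− libraries 7 and 8. A candidate explanation is that reads of ribosomal RNA were counted to Lars2, for which these values are what would be needed. The reads themselves were not analysed here, so a shared regulation of both genes stays open.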
